A study of Rattus norvegicus with 12 samples.

How the data were processed

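Heart tissue of rats was measured on 12 arrays of 1 colour, 6 of failing and 6 of control hearts, and each sample's group and replicate number were taken from its title. Per the labels' protocols, total RNA was extracted with Trizol, cleaned on RNeasy columns, and turned into biotin-labelled cRNA from 6 µg of RNA. The protocol names 4 groups with 6 biological replicates each; the 2 that received captopril are not analysed here. A description field speaks of a cell line while the tissue field gives heart, and the samples were taken as heart tissue.

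The authors deposited 1 table of intensity values with 31099 probe sets and 12 columns, on a linear scale from 0.1 to 79913.6, and 0 of its columns belonged to no sample here. The submitters' processing notes name RMA, with no version. RMA output is usually given on a log2 scale and quantile normalized, whereas the deposited intensities are linear and have a mean, after trimming 2% from each end, between 500.19 and 500.23 on every array, as a global scaling to 1 target gives. Which summary method made the values therefore stays unknown. A scaling of this kind fixes each array's overall level, so a shift of most genes in 1 direction would not be seen. Median intensities ran from 120.8 to 144.2, and 28.1% to 31.7% of probe sets lay below an intensity of 50. There were no detection calls, scan dates or batches to use, and the number of arrays limits the precision. Fewer genes are measured well at the dim end, where small linear values spread widely after log2.

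The intensities were put on a log2 scale with no offset and no further normalization. A total of 57 control probe sets were left out of the tests, leaving 31042. The array annotation paired 20826 probe sets with 1 gene symbol, 436 with several, and listed 9780 with none; a gene was named only from probe sets with 1 symbol. The probe set with the highest mean over all 12 arrays stood for each of 14217 genes, 4525 of which had more than 1 probe set. Through their gene identifiers 14167 genes matched the RefSeq table of assembly GRCr8, which was used for names alone, and 0 symbols differed there. No coordinates are given, since the sources used here name no genome build.

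Failing and control hearts were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term) with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Log2 fold changes are failing minus control with the moderated SE of the fit over all genes, SDs are between the 6 hearts of a group, and folds are 2 to the power of the log2 fold change. A fit to the brighter genes, those with a mean over the 12 arrays at or above the median of all genes, 8.21 (intensity 297), was an alternative fixed before the data were examined. It is reported beside the fit over all genes because the latter gave no calls. All tests are two-sided.

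The 39 gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule names the 12 largest rises and 12 largest falls among called genes whose groups do not overlap, leaving out provisional symbols; 21 genes of heart failure in any case; and for each list up to 2 called genes in each direction, or the member with the smallest p. As no gene passed over all genes, the parts other than the always-named genes were applied to the brighter genes, a choice made after that was seen, and members with the smallest p over all genes are named too. Lists with at least 5 measured members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. A list score per heart, the mean of log2 values centred on each gene, was compared by an exact permutation test over all arrangements of 6 and 6, with a smallest two-sided p of 0.00216, adjusted over 39 lists. Camera ranks a list against other genes, while the score test asks whether the hearts separate. Some lists share genes.

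Alternatives covered the filter on dim genes, the variance model, array weights, quantile normalization, median centring, an exact rank-sum permutation test, the mean of all probe sets, stricter thresholds, the replicate number as a term, an RNA quality covariate from the 3' minus 5' difference of Gapdh and beta-actin control probe sets, and leaving out each heart. An offset of 32 before log2, refits within the brighter genes, and tests of lists and of named genes without each heart were added after the data were seen. Figures were drawn with matplotlib 3.10.9.

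The fits were tested on simulated data made from the real means and spreads, with 50 genes changed at each of 4 sizes. The noise was normal and independent between genes, whereas real genes vary together (estimated correlation 0.861 in the respiratory chain list). The rates given next therefore need not hold for the real data. Over all 14217 genes the fit recovered 14%, 52%, 76% and 88% of changes of 0.5, 1, 2 and 3 (log2), with 4 other genes called. Of the changed genes, 28, 32, 25 and 25 lay among the 7109 brighter genes, where the fit recovered 28.6%, 78.1%, 100% and 100% of them, with 2 other genes called. Splits of the samples were drawn with seed 1, 100 of the 462 possible.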

Results

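Messenger RNA was profiled in heart tissue of rats with a 1-colour 3' oligonucleotide array, 1 array for each heart. The groups held 6 failing and 6 control hearts, which the labels call biological replicates. The series concerns the spontaneously hypertensive rat (SHR), an inbred strain that develops high blood pressure, and the onset of heart failure in it. The comparison asks which transcripts differ between failing and control hearts. The strain and age of the control animals are not given in the sources used here. Of the 31042 probe sets on the table, 20826 carried 1 gene symbol, and these gave 14217 genes. All arrays had been scaled alike, to a trimmed mean intensity between 500.19 and 500.23, and their median intensity lay between 120.8 and 144.2. The number of arrays limits the precision. Spearman correlations between arrays ranged from 0.915 to 0.945, and no pair of arrays held identical values.

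Lists of secreted matrix proteins, fibroblast genes, TGF-beta pathway genes and complement genes lay higher in failing than in control hearts, each with an adjusted p of 0.0211 by an exact permutation test on scores over 39 lists. All 4 calls ended without control replicate 1 or 6 (adjusted p from 0.0563 to 0.0675), and camera's ended with an estimated correlation (adjusted p from 0.238 to 0.262). Fibronectin (Fn1) was 3.47-fold and osteopontin (Spp1) 3.99-fold higher in failing hearts, n = 6 in each group, by limma among the brighter genes, defined below. The Spp1 call ended without failing replicate 3 or 4 or control replicate 1 or 6 (adjusted p from 0.0517 to 0.0552). The 3 lists of mitochondrial energy metabolism lay lower by camera, but none passed the score test (adjusted p = 0.184) or camera with an estimated correlation (adjusted p from 0.456 to 0.486), and 2 of 34, 4 of 71 and 3 of 27 brighter members fell. The difference was larger without control replicate 4, which lay among the failing hearts, though whether through the heart or its array was not tested. In the probe sets used, the atrial and B-type natriuretic peptides (Nppa, Nppb) and beta-myosin heavy chain (Myh7) were at nearly equal, very high levels in both groups. No gene passed an adjusted p of 0.05 in the limma fit over all 14217 genes (0 higher, 0 lower, lowest adjusted p = 0.0671), although 2710 genes had an unadjusted p under 0.05, against 711 that chance alone gives on average. Because genes vary together, the number by chance can lie far from that average, and it was not counted over other splits of the hearts. Of the 2710, 1296 were higher and 1414 lower in failing hearts. An exact rank-sum permutation test had 2517 genes at an unadjusted p under 0.05 and called 0, a count that says little, since its smallest p of 0.00216 passes over 14217 genes when 616 genes reach it, and 284 did.

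Dim transcripts varied far more between hearts than bright ones. The median residual SD was 0.784 (log2) among dimmer genes and 0.236 among the brighter genes. Among the brighter genes alone, the 7109 at or above the median level (mean log2 intensity of at least 8.21), limma called 384 genes higher and 336 lower in failing hearts (lowest adjusted p = 0.00941). The groups did not overlap in 230 of all 7109 brighter genes, against the 15.4 (0.216%) that chance gives on average, a number that was not counted over other splits either. The calls were 53.3% higher genes, and 64.4% after each array was centred on its median (333 higher, 184 lower). Leaving out any 1 heart other than failing replicate 2 moved at least 1 of these counts by over 1.5 times. They ranged from 131 higher and 46 lower, without failing replicate 3 and control replicate 1 in turn, to 726 higher and 962 lower without control replicate 4. All 720 genes were called without control replicate 4 too. Probe sets gave 0 calls over all 31042 (lowest adjusted p = 0.1, 4495 at an unadjusted p under 0.05) and 429 higher and 230 lower among the brighter probe sets. Because no gene passed over all genes, genes are described below as having risen or fallen when they passed among the brighter genes, a use of that fit chosen after the result over all genes was seen. Of the 88 such genes named here, 42 were called whichever 1 heart was left out, and 46 lost their call without at least 1 heart. The most were lost in 3 fits, 44 without control replicate 1, 44 without control replicate 6 and 42 without failing replicate 3.

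**Figure D1:**
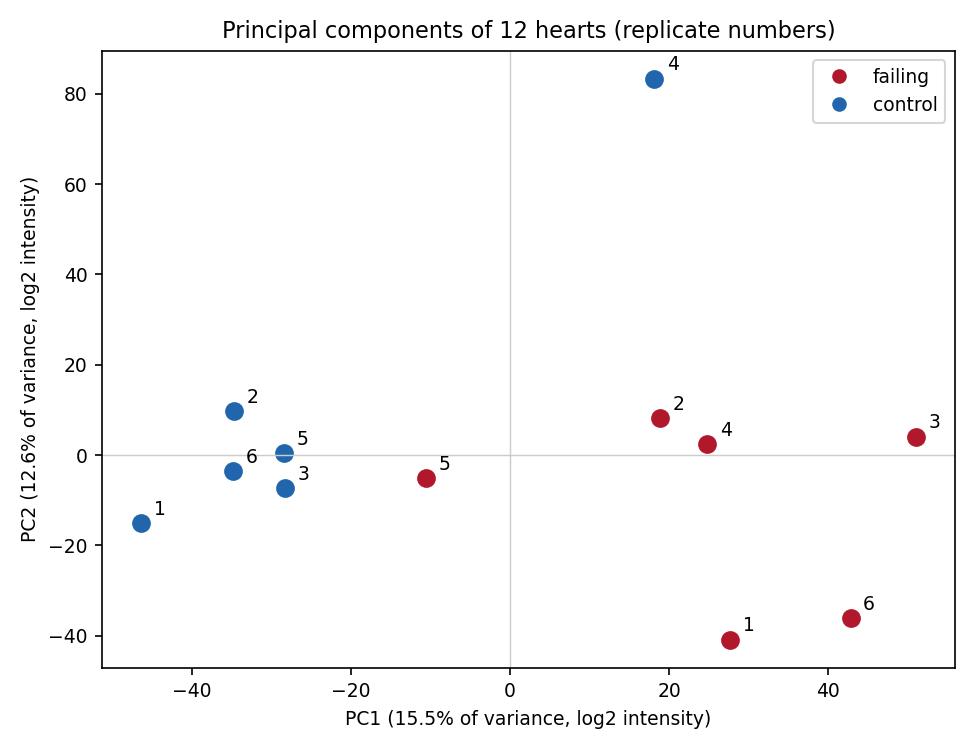
Principal components of log2 intensity over 14217 genes, with each point a heart, numbered by replicate, red for failing and blue for control. The first component (15.5% of variance) places 5 failing hearts above 0 and failing replicate 5 at -10.6, and the second (12.6%) sets control replicate 4 apart at 83.3.

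The first principal component held 15.5% of the variance and parted the groups except for 2 hearts. Failing replicate 5 lay at -10.6, on the side of the control hearts, and control replicate 4 at 18.1, on the side of the failing hearts. The second component, with 12.6% of the variance, separated control replicate 4 from all others.

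Among genes whose groups did not overlap, the largest rises among the brighter genes were those of Hamp (2.09 ± 0.37), the iron-regulating peptide hepcidin, Cdo1 (1.69 ± 0.37), cysteine dioxygenase, and Thbs4 (1.68 ± 0.36), a thrombospondin of the extracellular matrix (log2 fold change ± SE, n = 6 per group). Next came the stress-response gene Nupr1 (1.59 ± 0.28), Enc1 (1.59 ± 0.29), Tmem100 (1.54 ± 0.27), the matricellular gene Ccn3 (1.54 ± 0.32) and the transcription factor gene Cebpd (1.49 ± 0.26). The proteoglycan versican (Vcan, 1.42 ± 0.23), Dkk3 (1.41 ± 0.23), Olfml3 (1.32 ± 0.27) and Plb1 (1.29 ± 0.27) completed the 12. Their limma adjusted p among the brighter genes lay between 0.00941 and 0.0159, and all 6 failing hearts exceeded every control heart for each, as the choice of these genes required. The largest falls were smaller. Rev3l (-1.28 ± 0.22), the catalytic subunit of DNA polymerase zeta, and Mmp15 (-1.10 ± 0.22), a membrane-bound matrix metalloproteinase, led them, followed by Cmpk2 (-0.89 ± 0.21), Dusp23 (-0.89 ± 0.16), Lpar6 (-0.86 ± 0.21) and Ppargc1b (-0.76 ± 0.13), a coactivator of mitochondrial gene expression. Acyp1 (-0.75 ± 0.15), Pitpnc1 (-0.74 ± 0.17), Zfp955a (-0.68 ± 0.15), smoothelin (Smtn, -0.67 ± 0.16), Atg4d (-0.66 ± 0.12) and Pmm2 (-0.64 ± 0.12) fell by less, with adjusted p from 0.00988 to 0.0216 over these 12.

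**Figure D2:**
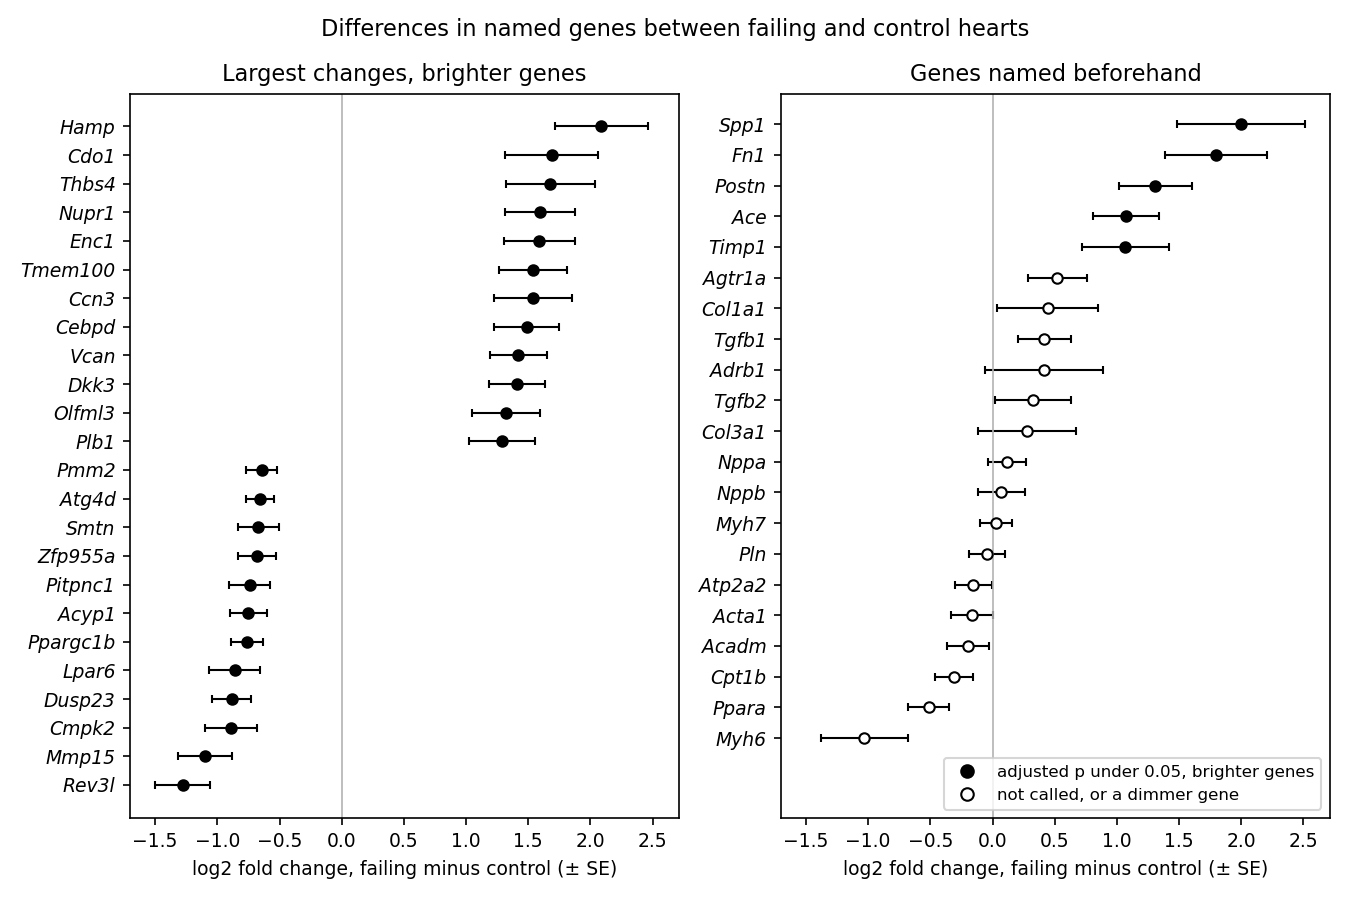
Log2 fold change, failing minus control, with SE bars for the 12 largest rises and 12 largest falls of the brighter genes (left) and the 21 genes named before the data were examined (right), 6 hearts per group. Filled points passed an adjusted p of 0.05 among the brighter genes, and open points did not or lay among the dimmer genes. Spp1, Fn1, Postn, Ace and Timp1 are the filled points on the right, while Nppa, Nppb and Myh7 lie near 0.

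The list of non-collagen matrix proteins lay 0.76 (log2) higher in failing hearts, with scores of 0.38 ± 0.36 against -0.38 ± 0.18 (SD, n = 6, exact permutation p = 0.00216, the smallest that permutations can give here, adjusted p = 0.0211 over 39 lists, and 0.0633 without control replicate 1 or 6). Its members were 22 higher and 1 lower of 39 measured members adjusted over the list alone, and 14 higher and 1 lower of 31 among the brighter genes. Over all genes 0 members of this or any other list passed. Spp1 (2.00 ± 0.52), Fn1 (1.80 ± 0.41), which exceeded every control heart in 5 of 6 failing hearts, periostin (Postn, 1.31 ± 0.29) and fibulin 2 (Fbln2, 1.11 ± 0.17) rose (adjusted p = 0.0239, 0.0162, 0.0162 and 0.00941 among the brighter genes), and vitronectin (Vtn, -0.61 ± 0.14) fell. The preset-correlation list test gave camera adjusted p = 7.38e-15, and adjusted p = 0.238 with an estimated correlation.

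The collagen list lay 0.53 higher, which did not pass the exact permutation test (exact p = 0.0758, adjusted p = 0.184), with camera adjusted p = 2.00e-04, and adjusted p = 0.454 with an estimated correlation. It had 6 higher and 0 lower of 20 measured members adjusted over the list alone, and 3 higher and 0 lower of 16 among the brighter genes. Col5a2 (1.18 ± 0.30) and Col18a1 (0.70 ± 0.20) rose, whereas the fibrillar collagens of types I and III differed by less than the spread between hearts, 0.44 ± 0.40 for Col1a1 (adjusted p = 0.437) and 0.28 ± 0.39 for Col3a1 (adjusted p = 0.624). Without failing replicate 1, the lowest failing heart for both, their differences were larger but still did not pass (limma adjusted p = 0.131 for each). Col5a3 had the smallest p of the list but was dim, at 6.40 ± 1.03 in failing and 3.35 ± 1.13 in control hearts (log2; adjusted p = 0.0729 over all genes, and 0.0424 without control replicate 4). Collagen processing and cross-linking genes had 3 higher and 0 lower of 17 measured members adjusted over the list alone, and 3 higher and 0 lower of 14 among the brighter genes (0.30, exact permutation p = 0.0758; camera adjusted p = 0.00234, and adjusted p = 0.412 with an estimated correlation), among them lysyl oxidase, Lox (1.55 ± 0.37), and Plod2 (0.77 ± 0.23). Matrix proteases and inhibitors moved both ways, with 11 higher and 3 lower of 38 measured members adjusted over the list alone, and 10 higher and 2 lower of 22 among the brighter genes (0.18, exact permutation p = 0.0325; camera adjusted p = 0.00144, and adjusted p = 0.238 with an estimated correlation). Cathepsins S (Ctss, 1.23 ± 0.29) and K (Ctsk, 1.22 ± 0.26), gelatinase A (Mmp2, 0.89 ± 0.17) and the protease inhibitor Timp1 (1.07 ± 0.35) rose, and Mmp15 and Adam19 (-0.76 ± 0.23) fell. The Timp1 call (adjusted p = 0.047) ended without any 1 of 9 hearts (adjusted p from 0.0704 to 0.102). Of 3 further Adam19 probe sets, 1 dim one went the other way at an unadjusted p under 0.05.

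The list of TGF-beta and BMP signalling genes lay 0.45 higher in failing hearts (exact permutation p = 0.00216, adjusted p = 0.0211, and 0.0633 and 0.0563 without control replicates 1 and 6 in turn), with camera adjusted p = 1.31e-09, and adjusted p = 0.238 with an estimated correlation. The list had 13 higher and 0 lower of 46 measured members adjusted over the list alone, and 9 higher and 0 lower of 33 among the brighter genes. The latent TGF-beta binding protein gene Ltbp2 (1.40 ± 0.35) and Tgif1 (1.04 ± 0.21) rose most. The ligand genes themselves did not pass, at 0.42 ± 0.21 for Tgfb1 (adjusted p = 0.168, and 0.046 without control replicate 4) and 0.32 ± 0.31 for Tgfb2 (adjusted p = 0.452). Grem1, a BMP antagonist, had the smallest p of the list at intensities near the bottom of the scale (4.40 ± 1.31 in failing and 0.77 ± 0.79 in control hearts, log2; adjusted p = 0.0671 over all genes, and 0.034 without control replicate 4), where no fold is given. The list of fibroblast markers outside the matrix lay 0.48 higher (exact permutation p = 0.00216, adjusted p = 0.0211, and 0.0675 and 0.0563 without control replicates 1 and 6; camera adjusted p = 2.14e-06, and adjusted p = 0.262 with an estimated correlation). The list had 7 higher and 0 lower of 27 measured members adjusted over the list alone, and 7 higher and 0 lower of 16 among the brighter genes. Pi16 (2.18 ± 0.71), S100a4 (1.17 ± 0.26) and vimentin (Vim, 0.78 ± 0.16) were the leading members. Pi16 split the control hearts, at 6.94, 7.47 and 8.47 in replicates 1, 2 and 5 and 10.78, 10.85 and 10.83 in replicates 3, 4 and 6 (log2). Failing hearts began at 10.81. Its limma call (adjusted p = 0.0455 among the brighter genes) held without control replicate 3 or 4 or failing replicate 5. It ended without any other 1 heart (adjusted p from 0.0517 to 0.0995).

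**Figure D3:**
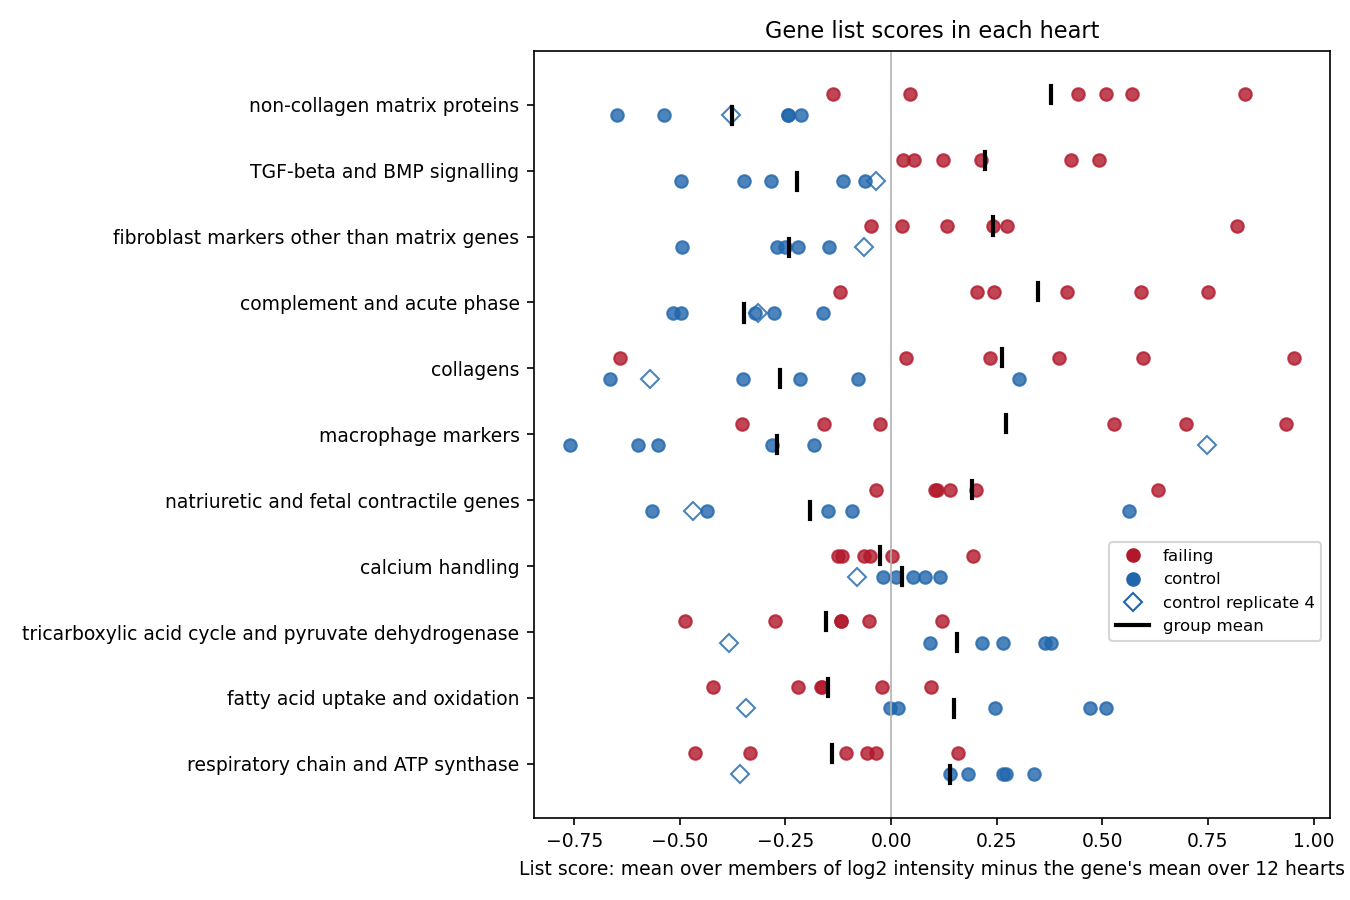
Scores of 11 gene lists in each heart, the mean over members of log2 intensity minus each gene's mean over the 12 hearts, with red points for failing hearts, blue for control hearts, an open diamond for control replicate 4 and black bars for group means. Failing and control hearts do not overlap in the upper 4 lists, while control replicate 4 lies among the failing hearts in the lower 3.

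The complement and acute phase list lay 0.70 higher (exact permutation p = 0.00216, adjusted p = 0.0211, and 0.0633 and 0.0563 without control replicates 1 and 6; camera adjusted p = 5.10e-09, and adjusted p = 0.238 with an estimated correlation), with 14 higher and 0 lower of 27 measured members adjusted over the list alone, and 11 higher and 0 lower of 14 among the brighter genes. Lipopolysaccharide binding protein, Lbp (2.51 ± 0.45), and ceruloplasmin, Cp (1.14 ± 0.23), rose most. Macrophage markers lay 0.54 higher without passing the exact permutation test (exact p = 0.0952; camera adjusted p = 6.03e-07, and adjusted p = 0.412 with an estimated correlation). They had 13 higher and 0 lower of 29 measured members adjusted over the list alone, and 9 higher and 0 lower of 22 among the brighter genes, led by galectin 3 (Lgals3, 1.24 ± 0.31) and Ctss. Control replicate 4 stood at 0.75 on this score, among the highest hearts of either group, and without it 15 macrophage genes were higher over the list alone. Cytokines and chemokines (0.17, exact p = 0.353; camera adjusted p = 0.0539) had 2 higher and 1 lower of 51 measured members adjusted over the list alone, and 4 higher and 0 lower of 19 among the brighter genes, and Icam1 (0.80 ± 0.23), Il1r1 (0.72 ± 0.20) and Tnfrsf1a (0.66 ± 0.16) rose. Camera called them without control replicate 2 or failing replicate 1, 5 or 6 (adjusted p from 0.00276 to 0.046), but not with an estimated correlation (adjusted p = 0.502, and from 0.277 to 0.553 without these hearts). Their mean was 0.32 without failing replicate 1 and 0.10 without failing replicate 3. Interferon response and antigen presentation genes (-0.013, exact p = 0.929, as low as -0.078 without failing replicate 2, and above 0 without control replicate 2 or failing replicate 1 or 6, at 0.042, 0.069 and 0.055) had 0 calls in either direction, RT1-DMa having their smallest p (1.05 ± 0.28, adjusted p = 0.0975 over all genes). Mast cell and granulocyte markers averaged -0.024 (exact p = 0.937), where camera pointed up. Quantile normalization turned the mean to 0.031 and leaving out control replicate 1, 3 or 4 or failing replicate 3 or 4 to between 0.0094 and 0.12. It was -0.15 without control replicate 6, and Lcn2 (0.76 ± 0.25) alone rose. T, B and NK cell markers averaged -0.52 (exact p = 0.37) with 0 calls, and -0.082 without control replicate 4, whose score was 2.45. Only 1 of 24 lay among the brighter genes. Cd8a had their smallest p (-2.07 ± 0.67, adjusted p = 0.138 over all genes). It ran from 2.07 to 6.43 in failing hearts (log2), near the bottom of the scale, where the size of a difference is uncertain.

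Of the genes that mark fetal reprogramming of the heart, the best known did not pass the threshold. Nppa was at 15.70 ± 0.22 in failing and 15.58 ± 0.29 in control hearts (SD, log2), a difference of 0.12 with a 95% interval from -0.22 to 0.45. Nppb differed by 0.070 ± 0.19, Myh7 by 0.029 ± 0.13 and skeletal alpha-actin (Acta1) by -0.16 ± 0.17, with adjusted p from 0.505 to 0.901 among the brighter genes. These 4 genes lay between 14.7 and 15.7 (log2), close to the highest intensities on the arrays. A second Myh7 probe set, at 14.5, gave 0.32 ± 0.14 (limma unadjusted p = 0.0497, adjusted p = 0.345 over all probe sets, where none passed). Alpha-myosin heavy chain, Myh6, was -1.03 ± 0.35 in failing against control hearts (adjusted p = 0.0533 among the brighter genes, 0.012 without control replicate 4, 0.0105 without failing replicate 5 and 0.00415 with array weights), and its second probe set gave -1.59 ± 0.52. Cross-hybridisation between Myh6 and Myh7, and between the actin genes, cannot be ruled out from these values. The natriuretic and fetal list lay 0.38 higher (exact permutation p = 0.0801; camera adjusted p = 0.0114, and adjusted p = 0.391 with an estimated correlation) with 3 higher and 0 lower of 17 measured members adjusted over the list alone, and 3 higher and 0 lower of 14 among the brighter genes. Myl1 (1.12 ± 0.30) and Actn1 (0.91 ± 0.24) rose. Camera's call was lost without control replicate 4 (adjusted p = 0.135), and the exact permutation test called the list without control replicate 3 (adjusted p = 0.0281). The list shares 3 genes with the atrial markers, which that test also called without this heart. Of its members, Myl4 and Myl7 stood at 12.59 and 13.38 in control replicate 3 and at 11.32 and 11.83 in failing replicate 5 (log2). The other 10 hearts reached at most 9.89 and 9.48.

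Adult sarcomere and Z-disc genes averaged -0.12 (exact permutation p = 0.366; camera adjusted p = 0.228) with 0 calls. Without control replicate 4, the lowest control heart on this score, the mean was -0.22 (camera adjusted p = 0.00316, and adjusted p = 0.509 with an estimated correlation; exact permutation adjusted p = 0.107) and 5 brighter members were lower and 1 higher. Without failing replicate 3 the mean was -0.063 (camera adjusted p = 0.69). The calcium handling list averaged -0.053 (exact p = 0.366, camera adjusted p = 0.203). Its mean was -0.097 without failing replicate 5, and -0.033, -0.035 and -0.035 without failing replicate 3, failing replicate 6 and control replicate 3. It had 0 higher and 1 lower of 39 measured members adjusted over the list alone, and 1 higher and 3 lower of 30 among the brighter genes. The T-type calcium channel gene Cacna1g (1.15 ± 0.32) rose, and Hrc (-0.94 ± 0.30) and junctophilin 2 (Jph2, -0.63 ± 0.20) fell. Asph (-0.51 ± 0.11) had the smallest p, but 2 of its 3 other probe sets went up. The calcium pump Atp2a2 (-0.15 ± 0.15, adjusted p = 0.469, and 0.0991 without control replicate 4) and phospholamban (Pln, -0.044 ± 0.15, adjusted p = 0.856) did not pass. Another Atp2a2 probe set, at 12.6, gave -0.27 ± 0.11 (limma unadjusted p = 0.0257, adjusted p = 0.277 over all probe sets, where none passed), and its dim ones ran from -0.63 ± 0.40 to 0.53 ± 0.44. For Pln a dim probe set, at 6.04, gave -2.19 ± 0.61 (limma unadjusted p = 0.00411, adjusted p = 0.169 over all probe sets) and a bright one, at 14.9, gave 0.019 ± 0.14. Cardiac ion channel and gap junction genes averaged -0.21 (exact p = 0.0455, adjusted p = 0.184 over 39 lists), with 0 higher and 2 lower of 40 measured members adjusted over the list alone, and 0 higher and 0 lower of 19 among the brighter genes. Without control replicate 4 the list was called (exact permutation adjusted p = 0.0469; camera adjusted p = 0.0282, and adjusted p = 0.37 with an estimated correlation), with 8 lower over the list alone and 6 among the brighter genes. Kcnd2 (-1.66 ± 0.25), a transient outward potassium channel gene among the dimmer genes, was lower in all 6 failing hearts than in any control heart (adjusted p = 0.0671 over all genes, and 9.44e-04 without control replicate 4). Renin-angiotensin, endothelin and adrenergic genes (0.14, exact p = 0.175; camera adjusted p = 0.0539, and from 0.0272 to 0.0472 without control replicate 2, 3 or 6 or failing replicate 2 or 5) had 3 higher and 0 lower of 43 measured members adjusted over the list alone, and 6 higher and 0 lower of 15 among the brighter genes. With an estimated correlation camera did not call them (adjusted p = 0.347, and from 0.162 to 0.373 without these hearts). Their mean was 0.087 without control replicate 1. Angiotensin-converting enzyme (Ace, 1.07 ± 0.27, adjusted p = 0.0219, and from 0.0501 to 0.0552 without control replicate 1 or 6 or failing replicate 3) and Hsd11b1 (1.41 ± 0.25), which regenerates active glucocorticoid, rose. The angiotensin receptor Agtr1a (0.52 ± 0.24) and the beta-1 adrenoceptor Adrb1 (0.42 ± 0.47) lay among the dimmer genes and did not pass over all genes (adjusted p = 0.262 and 0.669). The hypertrophic growth list had a median of -0.083 and a mean of 0.058 (exact p = 0.266), opposite in sign, with 3 higher and 1 lower of 53 measured members adjusted over the list alone, and 5 higher and 2 lower of 41 among the brighter genes. That mean was 0.033, 0.035 and 0.092 without control replicates 1, 4 and 5 in turn. Igfbp6 (1.20 ± 0.28) and Rgs2 (0.92 ± 0.23) rose, and Ppargc1b and the mitochondrial transcription factor Tfam (-0.38 ± 0.12) fell.

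Energy metabolism genes lay lower in failing hearts by camera, at -0.30 for fatty acid uptake and oxidation (camera adjusted p = 1.43e-05, and adjusted p = 0.456 with an estimated correlation), -0.28 for the respiratory chain and ATP synthase (camera adjusted p = 3.02e-10, and adjusted p = 0.486 with an estimated correlation), and -0.31 for the tricarboxylic acid cycle and pyruvate dehydrogenase (camera adjusted p = 4.00e-06, and adjusted p = 0.456 with an estimated correlation). None passed the exact permutation test on scores (exact p = 0.0801, 0.0779 and 0.0628). Among the brighter genes 2 of 34 fatty acid genes, 4 of 71 respiratory chain genes and 3 of 27 tricarboxylic acid cycle genes fell, and none rose. Adjusted over the list alone the counts were 0, 0 and 2. Hadh (-0.92 ± 0.26) and Acsl1 (-0.60 ± 0.18) of fatty acid oxidation, Ndufs8 (-0.71 ± 0.20) and Ndufa11 (-0.52 ± 0.13) of complex I, and Pdp2 (-0.83 ± 0.22), Idh3b (-0.59 ± 0.18) and Idh3a (-0.57 ± 0.15) fell. Ndufv3 (-0.64 ± 0.20) fell too, though its second probe set went up. Control replicate 4 scored -0.34, -0.36 and -0.38 on these 3 lists, among the failing hearts. Without it 18 of 37, 51 of 71 and 20 of 28 measured members were lower adjusted over the list alone. The brighter genes then included 15, 36 and 19 falls, and the list means were -0.40, -0.38 and -0.42 (exact permutation adjusted p = 0.0591, 0.0362 and 0.0362). Of the genes named beforehand, Cpt1b, which admits fatty acids to mitochondria, was at -0.31 ± 0.15 (adjusted p = 0.159, and 0.0137 without control replicate 4). Acadm was at -0.20 ± 0.17 (adjusted p = 0.41, and 0.0449 without it). Ppara, among the dimmer genes, was at -0.51 ± 0.16 (adjusted p = 0.135 over all genes). Glycolysis and glucose uptake averaged -0.025 (exact p = 0.745), and ran from -0.057 without control replicate 4 to 0.022 without failing replicate 3, with 0 higher and 0 lower of 27 measured members adjusted over the list alone, and 2 higher and 1 lower of 22 among the brighter genes: Slc2a1 (0.76 ± 0.22) and Eno2 (0.72 ± 0.21) rose, and Pfkm (-0.61 ± 0.20) fell.

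Among markers of other cell types, endothelial markers averaged 0.096 (exact permutation p = 0.149) with 3 higher and 1 lower of 28 measured members adjusted over the list alone, and 3 higher and 2 lower of 25 among the brighter genes. Without control replicate 4, the highest heart on this score, the mean was 0.15 and the list was called (exact permutation adjusted p = 0.0338), with 7 higher and 2 lower over the list alone. Von Willebrand factor (Vwf, 1.10 ± 0.24) and endoglin (Eng, 0.52 ± 0.14) rose, and Emcn (-0.78 ± 0.20) and Ets1 (-0.54 ± 0.17) fell. Smooth muscle and pericyte markers averaged 0.26 (exact p = 0.0195, adjusted p = 0.127; camera adjusted p = 0.00835, and adjusted p = 0.412 with an estimated correlation). Tagln (0.99 ± 0.30) and Pdgfrb (0.59 ± 0.17) rose there and Smtn fell. Atrial markers averaged 0.28 (exact p = 0.152; camera adjusted p = 0.0387, and adjusted p = 0.391 with an estimated correlation), and 0.43 without control replicate 3. Camera's call was lost without control replicate 2 or 4 or failing replicate 1 or 4 (adjusted p from 0.0597 to 0.166), the exact permutation test called the list without control replicate 3 (adjusted p = 0.0281), and only Hamp and Dkk3 of 15 members among the brighter genes rose. Nerve and Schwann cell markers averaged 0.25 (exact p = 0.11; camera adjusted p = 0.00673, and adjusted p = 0.259 with an estimated correlation), and 0.15 without failing replicate 3. Uchl1 (1.03 ± 0.14) and Pmp22 (0.90 ± 0.15) rose. Cartilage and bone genes averaged 0.30 (exact p = 0.113; camera adjusted p = 0.0419, and adjusted p = 0.412 with an estimated correlation), where Spp1 rose and Fmod (1.18 ± 0.27), among the dimmer genes, had the smallest p (adjusted p = 0.0791 over all genes, and 0.0483 without control replicate 4). That camera call was lost without control replicate 4 or 6 or failing replicate 3, 4, 5 or 6 (adjusted p from 0.0524 to 0.118). Skeletal muscle genes averaged -0.22 (exact p = 0.29), with -0.36 without failing replicate 5 and -0.13 without failing replicate 1. Myl1 and Mybpc2 (0.58 ± 0.15) rose. Adipocyte (0.039, exact p = 0.675), red cell and platelet (-0.31, exact p = 0.565), mesothelial and lung (-0.28, exact p = 0.026, adjusted p = 0.145) and cell cycle (-0.23, exact p = 0.623) lists had 0 calls among the brighter genes. Without control replicate 4 the red cell and cell cycle means turned to 0.039 and 0.055, and they ran down to -0.47 and -0.35 without control replicates 6 and 1. The red cell mean was -0.19 without failing replicate 6 and the cell cycle mean -0.12 without failing replicate 1. The adipocyte mean ran from -0.019 without control replicate 3 to 0.083 without control replicate 5. Without control replicate 2 the exact permutation test called the mesothelial and lung list (adjusted p = 0.0338). The smallest p of these 4 lists belonged to Plin1 (-1.80 ± 0.53), Car1 (-2.49 ± 0.60), Lrrn4 (-0.52 ± 0.16) and Mcm5 (-0.68 ± 0.27), none of which passed over all genes, though Car1 did without control replicate 4 (adjusted p = 0.0373). Plin1 (2.74 to 5.69 in failing hearts, log2) and Car1 (1.32 to 2.91) lay near the bottom of the scale, where the size of a difference is uncertain. Control replicate 4 was the highest of 12 hearts on the lymphoid, red cell, cell cycle, granulocyte, endothelial and apoptosis scores.

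Among stress and housekeeping lists, antioxidant and oxidant genes lay 0.28 higher (exact permutation p = 0.00649, adjusted p = 0.0506; camera adjusted p = 0.017, and adjusted p = 0.262 with an estimated correlation). Camera's call was lost without control replicate 4 or failing replicate 1 (adjusted p = 0.0881 and 0.0628), and the exact permutation test called the list without control replicate 3 or 4 or failing replicate 5 (adjusted p = 0.0362, 0.0422 and 0.0169). They had 3 higher and 0 lower of 31 measured members adjusted over the list alone, and 4 higher and 0 lower of 27 among the brighter genes, with extracellular superoxide dismutase (Sod3, 1.00 ± 0.15) and Gsta1 (0.97 ± 0.22) rising. Immediate early genes lay 0.25 higher (exact p = 0.104; camera adjusted p = 0.00234, and adjusted p = 0.412 with an estimated correlation), and 0.16 without control replicate 3. Cebpd and Cebpb (0.94 ± 0.29) rose. Cytoplasmic ribosomal protein genes, 0.087 (exact p = 0.171; camera adjusted p = 0.00393, and adjusted p = 0.502 with an estimated correlation) and 0.057 without failing replicate 3, had 0 members called, Rpl3 at 0.61 ± 0.23 (adjusted p = 0.0786, 0.00503 without control replicate 4 and 0.0427 without failing replicate 5). Proteolysis, atrophy and autophagy genes averaged 0.087 (exact p = 0.0476, adjusted p = 0.184), with Ctsl (0.57 ± 0.15) and Foxo3 (0.50 ± 0.14) rising. Unfolded protein response genes averaged 0.11 (exact p = 0.0714), with Dnajc3 (0.35 ± 0.11) rising. Circadian genes averaged 0.16 (exact p = 0.249), with Per2 (0.84 ± 0.26) rising. Apoptosis genes averaged 0.093 (exact p = 0.242), with Bcl2l2 (0.32 ± 0.10) short of the threshold (adjusted p = 0.0541, and 0.0313 without control replicate 4). The proteolysis mean was 0.052 without failing replicate 1. The circadian mean was 0.11 and 0.097 without failing and control replicate 6 in turn, and the apoptosis mean 0.060 and 0.14 without control replicates 1 and 4. Camera also called the unfolded protein response, apoptosis and cell cycle lists without failing replicate 1, failing replicate 6 and control replicate 1 in turn (adjusted p = 0.0215, 0.0349 and 0.0196), and not with an estimated correlation (adjusted p = 0.195, 0.405 and 0.618). In all, camera with its preset correlation called 16 lists higher and 3 lower of 39, an estimated correlation 0 (lowest adjusted p = 0.238, and 0.114 without 1 heart), the directional fry test 8, and the exact permutation test on scores 4. Without control replicate 4 the exact permutation test called 9, and without control replicate 1 or 6 it called 0. At least 19 camera calls arose in 7 of 100 splits of the 12 hearts, the real one included, with a median of 9 in the others.

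The spread between hearts was alike in both groups over all genes. The median ratio of failing to control SD was 0.997, and 1.17 without control replicate 4. The mean squared distance of a heart from its group mean was 0.408 in failing and 0.431 in control hearts (exact permutation p = 0.706, n = 6). Signs of RNA quality did not separate the groups: the 3' minus 5' difference of the Gapdh and beta-actin control probe sets averaged 0.55 ± 0.073 in failing and 0.56 ± 0.16 in control hearts (SD, log2, exact permutation p = 0.866).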

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

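The tests of blood, of the share of muscle cells, of RNA quality and of atrial tissue were chosen only after the values they use had been seen. The test of RNA quality replaced a planned covariate fit, which could decide nothing because the groups were nearly equal in that measure. The test of atrial tissue followed on 3 others: the group difference of Myl4, Myl7 and Sln alone decided nothing (0.43 ± 0.95 SE, exact permutation p = 0.665), and leaving out control replicate 3 and failing replicate 5, the hearts highest on Myl7, gave a matrix difference of 0.85 ± 0.18 while those 3 genes still differed by 0.82 (exact permutation p = 0.143). With the mean of those genes as a covariate the matrix difference was 0.745 ± 0.17. A heart is named here where its gap to the nearest heart of its group was so large a share of the group's range that it passed Dixon's 95% critical value for 6 samples. Chance gives that in about 1 of 20 groups of values, 16.1 of the 322 examined, and 39 were found, 18 of them in control replicate 4.

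Control replicate 4 stood highest of its group for the T, B and NK cell score (2.45), the red cell and platelet score (1.89), the cell cycle score (1.56), the endothelial score (0.20) and the cytoplasmic ribosomal protein score (0.15), and for Enc1 (9.78), Pitpnc1 (10.78), Hsd11b1 (12.02) and Rpl3 (14.49, log2). It stood lowest for the respiratory chain score (-0.36), the adult sarcomere score (-0.42), Myh6 (14.13), Atp2a2 (14.997), Cpt1b (13.13), Acadm (14.21), Kcnd2 (7.70) and the CreX spike-in (14.13). Its mean squared distance from the group mean, 0.596, was the largest of the control hearts. Its array also had the lowest maximum intensity (49903.5) and the highest median intensity (144.2) of the 12. An effect of the array on bright signals was not tested.

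Of the explanations for this heart, a shift of every dim gene goes against the scores of unrelated tissues, which moved little, at -0.037 for adipocyte, -0.066 for nerve and 0.18 for mesothelial and lung markers. Blood left in the vessels holds few dividing cells, whereas the cell cycle score exceeded the highest of the other 11 hearts by 1.28 times their whole range. That score was part of the pattern already seen, so it is no separate test, and blood was not decided. Red cell precursors may account for the red cell part: 5 of 7 further precursor genes were highest in this heart, and their median lay 2.36 (log2) above the other 5 control hearts, led by Klf1 (3.77) and Hemgn (3.75), though these 5 were dim and the 2 brighter ones, Tfrc (-0.38) and Sptb (-0.89), lay lower. They would not bring T and B cell transcripts, whose source stays open. Thymus tissue cannot be told apart from other lymphoid sources: the median difference of its genes, 0.148, lay under the bound set beforehand to exclude it, but only 3 genes were measured, all dim, with Bcl11b alone higher (3.63).

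The higher matrix, fibroblast and complement genes of failing hearts were weighed second. A lower share of muscle cells alone would raise markers of all other cells alike. The fibroblast score rose more than the endothelial score, by 0.39 ± 0.13 (SE, exact permutation p = 0.00649), and by 0.37 ± 0.13 without control replicate 4 (exact permutation p = 0.013). The fibroblast list was taken up because it had passed in these data. An unequal rise therefore does not exclude a lower share of muscle cells as part of the cause. The 3' minus 5' measure of RNA quality differed by -0.012 ± 0.073 (SE). For a bound, this difference and the slope of a score on it within groups were both taken 2 SE to the ends that give the most. The bounds were 0.302 of the 0.76 of the non-collagen matrix score and 0.195 of the 0.70 of the complement score. For the fibroblast score the bound was 0.299 of 0.48, over 50%. The slopes were uncertain, at -0.44 ± 0.73 for matrix, 0.21 ± 0.63 for complement and -0.70 ± 0.59 for fibroblast scores (SE), and were not refitted without single hearts. Such a bound also assumes a linear effect. RNA quality therefore cannot be told apart for any of these scores. Atrial tissue, by the mean of Myl4, Myl7 and Sln, had bounds made in this way of 0.320 for the matrix and 0.221 for the complement difference, under 50% of each. For the fibroblast score the bound, 0.268, was over 50%. The slopes lean on control replicate 3 and failing replicate 5, the hearts highest on Myl7, and were not refitted without them. The bounds therefore do not decide, and atrial tissue cannot be told apart for any of these scores. A hypothesis left open is a change of the fibroblasts themselves with heart failure, or a strain difference between the groups, neither of which could be tested here.

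Last, the nearly equal levels of Nppa, Nppb and Myh7 may reflect signals near the top of the scale. Compression there would shrink the spread between hearts, but the 34 genes at 15 or more (log2) had a median residual SD 1.09 times that of the 353 genes from 13 to 15, with a bootstrap 95% interval from 0.983 to 1.17. The ratio of 1 set beforehand to exclude compression was reached, but the interval includes 1. The bands also hold different genes, and the band from 13 to 15 may be compressed too. The spread includes control replicate 4, whose array had the lowest maximum intensity (49903.5). The ratio therefore sets no limit on the size of a compression, and compression was not decided. The less bright Myh7 probe set, at 14.5, gave a larger difference (0.32 ± 0.14) than the probe set used, at 15.7 (0.029). Array scaling was not decided. After quantile normalization the lowest limma adjusted p of the 3 genes was 0.549 among the brighter genes, and Nppb went from 0.070 to 0.135. That normalization also gives every array the same overall level, so a shift hidden by the deposited scaling would stay hidden. A control group whose hearts already expressed these genes highly is a biological explanation that was not tested.

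Control replicate 3 was far above its group on the atrial marker score (0.65), with Myl7 at 13.38 against at most 9.48 in the 10 hearts other than failing replicate 5 (11.83). Failing replicate 5 was the highest failing heart on the natriuretic and fetal score (0.63) and for Idh3a (12.54), and the lowest for vimentin (Vim, 13.86) and the antioxidant score (-0.094). Failing replicate 1 was highest for Hamp (12.27), the proteolysis score (0.22) and the 3' minus 5' differences of Gapdh (0.428), beta-actin (0.969) and their mean (0.698), and lowest for the unfolded protein response score (-0.18). Failing replicate 6 was highest for Slc2a1 (11.76) and lowest for Lpar6 (7.47), Pitpnc1 (9.004) and Car1 (1.32). Failing replicate 3 stood above its group on the fibroblast score (0.82), and failing replicate 2 below on the mesothelial and lung score (-0.51). Among control hearts, replicate 5 was apart for Adrb1 (4.17) and Col5a3 (5.55), replicate 2 for Grem1 (2.29) and replicate 1 for Dnajc3 (9.10).

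Splits of the 12 hearts into other groups of 6 and 6 were counted, 100 of them with the real one included. For the 720 genes called among the brighter genes, 1 split, the real one, gave as many, and the highest other gave 563. That other split exchanged only failing replicate 2 and control replicate 4. Chance is thus unlikely for the 720 calls but not excluded, since only 100 of the 462 possible splits were drawn. The fit to the brighter genes was also taken up only after the fit over all genes gave 0 calls. The counts of 0 genes and 0 probe sets cannot be tested in this way, since all 100 splits give at least 0 (highest other 1 and 3). For the 19 lists called by camera, 7 of 100 splits gave as many and the highest other gave 21, so chance is not excluded for that number.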

How the results depend on the processing

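The offset of 32, the refits within the brighter genes and the exact permutation tests on scores without 1 heart were chosen after the data were seen. The count of 0 genes over all genes depended on how dim genes and single hearts were treated, and the cause was not tested except that fewer and steadier genes enter that fit. It became 384 higher and 336 lower without the dimmer genes, 314 and 227 with a trended robust variance, 333 and 324 with array weights (control replicate 4 weighing 0.415), and 80 and 29 with the offset of 32. Probe sets gave 429 and 230, 373 and 175, and 35 and 11 with the filter, the trended variance and the offset. Leaving out 1 heart gave 0 to 294 higher genes and 0 to 382 lower genes (229 and 122 without failing replicate 5), and 0 to 120 higher and 0 to 40 lower probe sets. Among the brighter genes, array weights gave 862 higher and 1052 lower genes, median centring 184 lower, the mean of all probe sets 200 lower, the 0.01 threshold 18 and 5, a fold of at least 1.5 245 and 142, the exact rank-sum permutation test 0 and 0 (308 genes at its smallest p would pass, and 230 reached it), and leaving out 1 heart 131 to 726 higher and 46 to 962 lower. Of the genes these settings called over all genes that lay among the brighter genes, the fit to brighter genes also called 466 of 466 with the trended variance, 79 of 79 with the offset, 485 of 524 with array weights, 397 of 554 without control replicate 4 and 261 of 272 without failing replicate 5.

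Replicate numbers do not pair the hearts: correlations of same-numbered deviations ran from -0.031 to 0.075 and 2 of 6 failing hearts correlated best with their own number. With the replicate block 0 genes were called over all genes, and 276 were higher and 135 lower among the brighter genes.

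Of the primary lists, all kept their direction in 23 alternatives each. An estimated correlation ended camera's calls (0 of 39 lists) for the natriuretic and fetal (0.38), collagen (0.53), non-collagen matrix (0.76), TGF-beta (0.45), fatty acid (-0.30) and respiratory chain (-0.28) lists, whose means it leaves as they are. Fry called 8 lists and did not call the natriuretic and fetal, collagen, fatty acid and respiratory chain lists. Array weights (0.29) and leaving out control replicate 4 ended the natriuretic and fetal call, its mean running from 0.29 to 0.53 without 1 heart. The exact permutation test on scores called 0 to 9 lists without 1 heart, 0 without control replicate 1 or 6. The ratio of SDs within groups ran from 0.941 to 1.17 without 1 heart. Of 441 values of genes named beforehand, 416 kept their direction and side of the threshold, 16 passed it and 9 turned: Nppb (-0.024 to 0.19 without 1 heart), Myh7 (-0.049 to 0.085), Adrb1 (-0.0044 to 0.59) and Pln (-0.14 to 0.020, and 0.0057 after quantile normalization). Signal near the bottom of the scale limits what dim genes can show.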

Other observations

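Both tests of this part were written before their gene sets were scored, but the genes that prompted them had been seen. Many members also belong to the lists tested above. These are Sgk1, Per1, Mt1, Mt2A, Pdk4, Angptl4, Ddit4 and Dusp1 of the first set and Socs3, Il6st, Junb, Fgg, Fgb and Hp of the second. The sets are therefore not independent of those results. Among the genes higher in failing hearts were several that glucocorticoids are known to induce, Tsc22d3 at 1.11 ± 0.24 (log2 fold change ± SE), Hsd11b1, Cebpd and Lbp. A separate set of 13 glucocorticoid-responsive genes scored 0.66 ± 0.26 (SE) higher in failing hearts (exact permutation p = 0.0152, adjusted p = 0.0303 over 2 hypotheses, and p = 0.0303 without control replicate 4), and 4 of 6 failing hearts exceeded every control heart. Sgk1 (0.86 ± 0.31), Fkbp5 (0.84 ± 0.29), Errfi1 (1.20 ± 0.47), Ddit4 (0.76 ± 0.25) and Glul (0.55 ± 0.16) were higher at an unadjusted p under 0.05, and Glul alone passed among the brighter genes (limma adjusted p = 0.0332). Klf15 (0.062 ± 0.21), Pdk4 (0.074 ± 0.35) and Dusp1 (-0.16 ± 0.20), the only member that was lower, differed by less than their SE. A glucocorticoid response in failing hearts is a hypothesis that this test is consistent with, whether from the disease or from the handling of sick animals.

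An interleukin-6 type response was the second hypothesis for the same genes. Its 10 measured genes scored -0.048 ± 0.16 (SE, exact permutation p = 0.924), with Socs3 (0.75 ± 0.27), Stat3 (0.37 ± 0.14) and Il4r (0.41 ± 0.16) higher at an unadjusted p under 0.05. Fgb (-1.27 ± 0.59) and Pim1 (-0.84 ± 0.68) had the largest changes of the set and were lower, as were Fgg (-0.17 ± 0.53) and Hp (-0.013 ± 0.77), and 6 of the set lay among the dimmer genes. The set does not decide for or against it.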
